A study of Homo sapiens and Homo sapiens
Mus musculus with 47 samples.

How the data were processed

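Transcripts were measured in frozen postmortem hippocampus and prefrontal cortex of 2 donors with MATQ-Drop, a droplet method that reads total RNA and so also captures transcripts without a poly(A) tail. Per the labels' protocols, tissue was broken up in a Dounce homogenizer, fixed with paraformaldehyde and sorted by fluorescence into Hoechst-positive nuclei and Hoechst-negative material that the labels call synapses and that is called particles here. From donor 1 hippocampus, a further sort separated particles positive for both SYP, a synaptic vesicle protein, and PSD95, a scaffold of the postsynaptic density, from particles negative for both. A library of mixed nuclei of HEK293T, a human embryonic kidney line, and NIH/3T3, a mouse fibroblast line, tested the separation of barcodes. The 47 libraries were the mixed library, 3 and 2 of nuclei from donor 1 hippocampus and prefrontal cortex, 4 of nuclei from donor 2 hippocampus, 7 and 8 of particles from donor 1 hippocampus and prefrontal cortex, 7 and 7 of particles from donor 2 hippocampus and prefrontal cortex, and 4 and 4 of double-positive and double-negative particles. Cortical nuclei of donor 2 were not analysed here. In 16 libraries (library 4 of donor 2 hippocampal nuclei, the 7 of donor 2 hippocampal particles and the 8 of sorted particles) the title names hippocampus and the tissue field prefrontal cortex. These were grouped by title.

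Per the submitters' processing notes, the tools were cutadapt 3.1, UMI-tools, STAR 2.5.3a and featureCounts 2.0.1, with the builds hg19 and mm10. Their roles, options and use of strand, and any filter on barcodes before deposit, are not given in the sources used here. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, as the whole numbers and the listed tools show. The authors deposited exonic counts, intronic counts and their sum for nuclei and particles, and for the sorted libraries the sum alone. The sums matched in every value tested. Further deposited tables hold the long noncoding gene subset of the same counts. Mitochondrially encoded genes of the brain libraries are not analysed here, so the list of them has no result. The smallest number of detected genes per barcode was 610 in nuclei and 100 in particles, but 24 in double-positive and 4 in double-negative particles.

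Of 34,625 human gene IDs, 32,763 matched a symbol by Ensembl ID in a table of gene names, and a RefSeq gene table of assembly GRCh38.p14 gave gene classes and chromosomes. No genome sequence was used, and no coordinates are given. The 105 genes removed from every test were those on chromosome Y and some of the X inactivation centre. FTX, a gene of that centre and a member of a fixed list, was kept. Barcodes and libraries of a tissue specimen are not independent samples, so counts were summed per specimen (donor, region and fraction) for the tests between fractions and regions. Libraries of the same specimen are technical. The p-values of the gene tests measure the spread between specimens of 2 donors, or, for the sorted particles of donor 1, between libraries. Alternatives with sums per library or with each donor alone also took libraries as replicates.

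Differences between groups were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, on counts scaled by TMM and filtered by filterByExpr, with Benjamini-Hochberg adjustment and a threshold of 0.05 on adjusted p. Particles against nuclei used 4 particle and 3 nuclear sums with donor, region and fraction as terms. Hippocampal against cortical particles used 4 sums with donor and region as terms, which left 1 residual degree of freedom. Double-positive against double-negative particles used 4 and 4 libraries with no other term. Long noncoding RNAs in neuron-like against glia-like nuclei used 2 sums for each of 3 specimens, with specimen and class as terms and library sizes over all genes. Pairing came from the tissue: the sums of a specimen or donor share its deviations from the group means, with correlations across genes of 0.320, 0.483 and 0.247 for nuclei and particles of the 3 shared specimens, 0.103 for the regions of each donor, and 0.577, 0.699 and 0.492 for both classes of the 3 nuclear specimens. Levels are in CPM after TMM scaling unless said otherwise, and errors are SDs over specimens or libraries. The SE of a log2 fold change was not fitted directly. It is the absolute log2 fold change divided by the square root of the F statistic.

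Gene lists (17, of synaptic, dendritic, ribosomal, mitochondrial, nuclear, histone, glial, vascular, blood, long, immediate early and cytoskeletal genes) were tested with camera of limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The groups, tests, lists, named genes rule, cell type markers and first set of alternatives were fixed before the data were examined. List tests for the sorted particles were added afterwards. Some lists share genes, so their results are not independent. The dendritic list shares CAMK2A, SHANK1, SHANK3, DLG4, DLGAP3 and PPP1R9B with the postsynaptic list. It also shares ARC and BDNF with the immediate early genes, and KIF5C and KIF1A with the kinesins, dyneins and tubulins. With the preset correlation, camera compares the members of a list with the other genes. Its p then measures spread across genes and not between specimens or libraries. With an estimated correlation, camera's degrees of freedom are limited to the residual ones, 3 for particles against nuclei, 1 for regions and 6 for sorted particles. In the first 2 comparisons a list can then hardly pass, whatever its correlation, so a lost call there decides little. Named genes were the 10 largest log2 fold changes each way with adjusted p under 0.05, the same direction in every pair and a mean of at least 20 CPM, among protein-coding genes and long noncoding genes with a proper name. For each list, up to 4 members with the smallest p in the direction of the list median were named. Without a test, named genes were the 10 largest ratios each way among genes with at least 100 UMIs in both groups together and 10 in each. Members outside these rules are named where they went against their list, where they encode the proteins of the sort, or where a count of calls was small, and were chosen after their values were seen. Some genes that these rules pick are not reported here. A fold against a group at 0 counts is a bound against a floor of 3 counts over the group. The 95% intervals are Wilson intervals for shares and exact intervals for ratios of counts, and cover counting error only.

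Nuclei with at least 200 detected genes and, separately, particles with at least 100 were clustered with scanpy 1.11.5, scikit-learn 1.9.0 and leidenalg 0.10.2 on protein-coding genes (counts scaled to 10000 per barcode and log-transformed, 2000 variable genes, 30 components, 15 neighbours, resolution 1, seed 0). A cluster was called X-like where at least 3 markers of a fixed set, and at least 1 in 3 of the set, stood more than 2-fold above the mean of the other clusters (log2 of CPM + 5, at least 5 UMIs) and it held at least 20 barcodes. It stayed unnamed where another set had more markers among its 10 leading genes, or where its median UMI count was under 1 in 3 of that of its own specimen and none of its markers was among them. Long noncoding genes were kept out of the clustering, except that the pan-neuronal marker set holds MEG3, which is not reported between classes. Scrublet, run in scanpy per library, called 674 of 9800 nuclei doublets (6.88%; 0.169% to 18.5% per library). They were kept, and removed in an alternative.

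The intronic share was compared by an exact two-sided permutation test over the 35 splits of 7 sums, using scipy 1.17.1. Before use, each fit was tested on simulated counts with 200 changed genes. At simulated folds of 2 and 4 the fit recovered 19% and 83% for particles against nuclei (15,297 genes), 37% and 91% for regions (11,885 genes), 15% and 58% for sorted particles (2967 genes) and 14% and 70% for long noncoding RNAs (3027 genes), with 9.73%, 4.48%, 8.75% and 2.33% of calls false. With no simulated effect, camera called 0 of 15 lists for particles against nuclei (15,328 genes), 0 of 15 for regions (11,845 genes) and 3 of 12 for sorted particles (2946 genes). Simulated genes were drawn independently of each other, so these counts do not test the preset correlation. For regions of nuclei, 95.4% of the ratio intervals held the simulated fold (2000 genes). Alternatives changed the scaling (RLE), low-count filter, tool (DESeq2 1.42.0), covariates, exonic counts only, minimum genes per barcode (500 for nuclei, 200 for particles), unit of summing, clustering resolution (0.5 and 2), doublets and left-out specimens or libraries. Added after the data were seen were neuron-like nuclei only, libraries left out of specimen sums, libraries of each donor alone, equal depth of the sorted libraries, and for the lists the specimen pairs, the library sums and fits without donor. No pair of libraries of a group differed by less than sampling noise (chi-square per degree of freedom 1.32 to 5.00 over genes), so each counted separately. On log2 CPM, r per pair of double-negative libraries was -0.113 to 0.0220 over the 357 to 611 genes with at least 10 UMIs in the pair. At this depth such a floor can itself lower r, which was not tested, so poor agreement of these libraries stays open. In every other group it was at least 0.870 (at least 20 UMIs).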

Results

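The series compares RNA of single nuclei with that of Hoechst-negative particles sorted from the same human brain tissue, across hippocampus and prefrontal cortex, and asks further how particles carrying both synaptic proteins SYP and PSD95 differ from those carrying neither. Nuclei numbered 4435 in donor 1 hippocampus (3 libraries, 20,628,409 UMIs, median 2758 per nucleus), 1008 in donor 1 prefrontal cortex (2 libraries, 16,473,517 UMIs, median 9101.5) and 4357 in donor 2 hippocampus (4 libraries, 14,932,422 UMIs, median 2260). Particles were shallower. They numbered 4829 in donor 1 hippocampus (7 libraries, 3,392,511 UMIs, median 275), 2254 in donor 1 prefrontal cortex (8 libraries, 3,116,006 UMIs, median 464.5), 2646 in donor 2 hippocampus (7 libraries, 1,530,080 UMIs, median 260) and 1324 in donor 2 prefrontal cortex (7 libraries, 1,309,607 UMIs, median 305.5). The 4 double-positive libraries held 1917 particles and 1,374,039 UMIs (median 304), and the 4 double-negative libraries 289 particles and 49,638 UMIs (median 43), so that library sums ran from 9442 to 442453.

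In the mixture of human HEK293T and mouse NIH/3T3 nuclei, barcodes with at least 1000 UMIs nearly all belonged to 1 species. Of 191 such barcodes, 98 were human and 86 mouse at a purity of 90%, and 7 were mixed, so that 96.3% were pure (Wilson 95% interval 92.6 to 98.2) and the estimated rate of multiplets was 7.36%. UMIs of the other species made up a median of 0.310% in human and 0.392% in mouse barcodes. Over all 14,660 barcodes, of which 97.3% held under 100 UMIs, 25.7% were pure (Wilson 95% interval 25 to 26.4).

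Nuclei fell into 18 clusters that covered the main cell types of the tissue. Neuron-like nuclei made up 20.4% of donor 1 hippocampus (Wilson 95% interval 19.3 to 21.6), 45.1% of donor 1 prefrontal cortex (42.1 to 48.2) and 8.45% of donor 2 hippocampus (7.66 to 9.31). Oligodendrocyte-like nuclei made up 38.9%, 31.5% and 45.5% in the same order, and astrocyte-like nuclei 16.1% and 27.3% of the hippocampal specimens. The cortical oligodendrocyte-like share depends on the clustering: at resolution 0.5 it was 2.08%, and 31.6% of cortical nuclei lay in an unnamed cluster. Cortical nuclei held more excitatory neuron-like (30.7%) and inhibitory neuron-like (14.5%) nuclei than hippocampal nuclei of the same donor (14.8% and 5.59%). Microglia-like nuclei made up 12.2%, 4.76% and 7.28%, and oligodendrocyte precursor-like nuclei 9.09%, 6.25% and 7.39%. Endothelial or mural-like nuclei (0.406%, 2.18% and 0.115%) and T cell-like nuclei (0.203%, 0.298% and 0.597%) were rare, and no cluster was named ependymal. Cluster 14, led by F13A1 and STAB1 and holding 2.93% of nuclei, stayed unnamed. It had all 12 oligodendrocyte markers up beside the microglia markers APBB1IP, DOCK8 and CSF1R among its leading genes. Scrublet called 35.9% of its nuclei doublets, so a mixed origin stays open. Among named clusters it called 46.9% of cluster 16 (oligodendrocyte precursor-like, 49 nuclei) and 27.5% of cluster 7 (astrocyte-like, 545 nuclei). In cluster 10 (excitatory neuron-like) it was 19.9%, and in the other named clusters 0.355% to 17.8%. Doublets therefore stay open for part of the named classes too. Most oligodendrocyte-like nuclei lay in cluster 1 for donor 1 hippocampus, clusters 2 and 5 for donor 2 and cluster 12 for cortex, and excitatory neuron-like nuclei in clusters 10 and 11, 15, and 13. There is 1 specimen per tissue and donor, so shares were not tested. The Hoechst gate and the deeper cortical libraries can set them, and clustered alone donor 1 prefrontal cortex had 34.0% neuron-like nuclei.

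**Figure D1:**
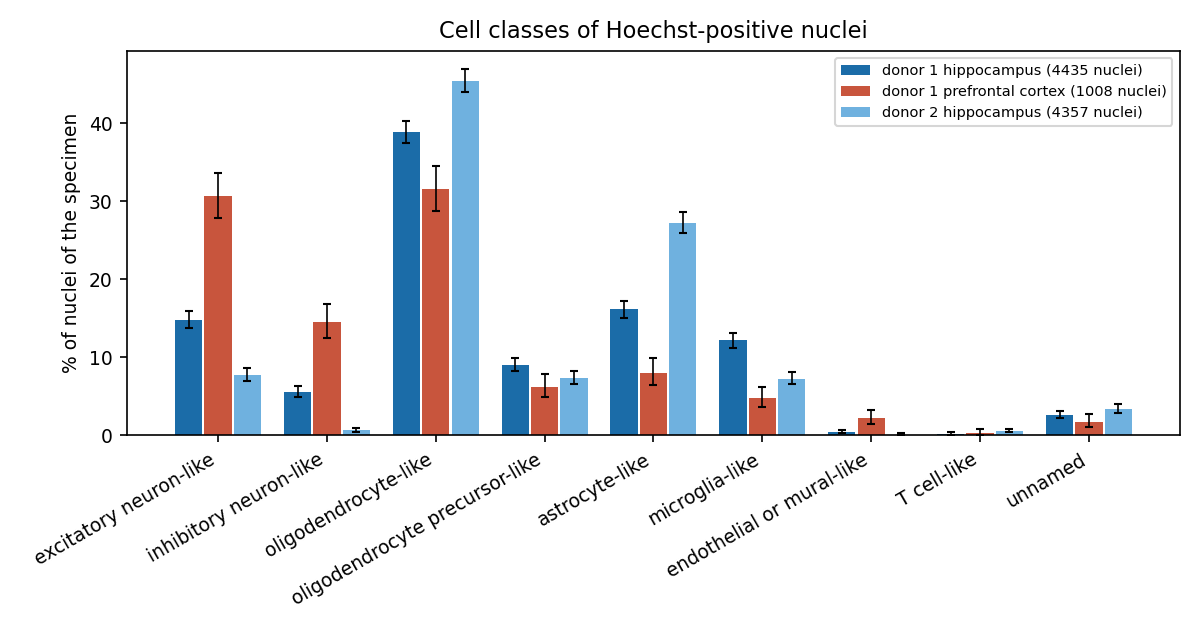
Share of nuclei in each named cell class (y axis, % of the nuclei of a specimen) for 3 specimens, with bars for shares and error lines for Wilson 95% intervals. Oligodendrocyte-like nuclei reach 38.9%, 31.5% and 45.5%, and excitatory neuron-like nuclei are most frequent in donor 1 prefrontal cortex at 30.7%.

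Intronic UMIs, which mark unspliced transcripts, made up most of the RNA of nuclei and little of that of particles. The share was 79.8%, 79.6% and 74.6% in nuclei of donor 1 hippocampus, donor 1 prefrontal cortex and donor 2 hippocampus (78.0% ± 2.91, SD, n = 3), against 4.98%, 6.91%, 9.47% and 8.79% in particles of donor 1 hippocampus, donor 1 prefrontal cortex, donor 2 hippocampus and donor 2 prefrontal cortex (7.54% ± 2.02, SD, n = 4). The gap of 70.5 percentage points was far larger than either spread and separated all 7 specimens. The exact two-sided permutation p was 0.0571, the smallest that 35 splits allow.

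**Figure D2:**
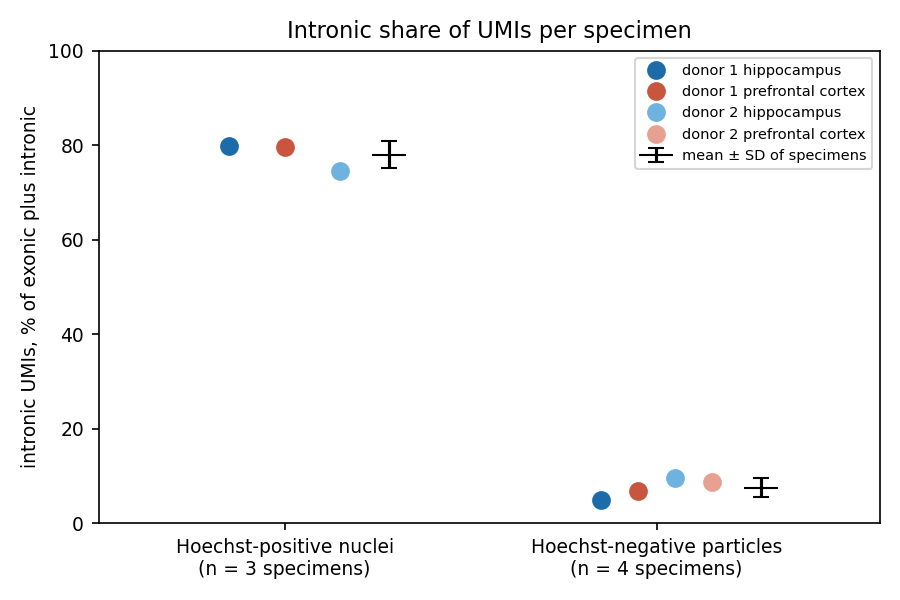
Intronic UMIs as % of exonic plus intronic UMIs (y axis) per specimen, for nuclei and particles (x axis); points are specimens, and the black marks show mean ± SD. The 3 nuclear specimens lie between 74.6% and 79.8% and the 4 particle specimens between 4.98% and 9.47%.

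Particles against nuclei asks which transcripts lie outside the nucleus. NEFH and NEFM, which encode neurofilament subunits, were 64.6-fold and 61.1-fold higher in particles (log2 6.01, SE 0.44, adjusted p = 5.99e-06, and log2 5.93, SE 0.39, adjusted p = 5.04e-06), at 461 ± 296 and 951 ± 359 CPM against 7.75 ± 5.43 and 16.2 ± 8.12 CPM in nuclei (SD, n = 4 and 3). NEUROD6 and BHLHE22, transcription factors of excitatory neurons, were 51.8-fold and 39.7-fold higher, and DDN, which encodes the dendritic protein dendrin, 45.7-fold. In the other direction, SLC5A11, a sodium-coupled inositol transporter, CD22, a sialic acid-binding lectin, CERCAM, RHBDF2, MYO15B, HSD17B3 and the long noncoding RNAs LINC00609, HPN-AS1, MIR219A2HG and LINC02882 were lower, with log2 fold changes from -6.63 (HSD17B3) to -5.64 (LINC02882) and adjusted p of at most 1.36e-05. HSD17B3 had 4 UMIs in all particles together. SLC5A11, CD22, CERCAM and HSD17B3 were leading genes of oligodendrocyte-like nuclear clusters, and MIR219A2HG and HPN-AS1 were higher in glia-like than neuron-like nuclei. Cell makeup therefore bears on these genes, and their lower level in particles need not mean retention in the nucleus. All 20 named genes kept their call against neuron-like nuclei only. The long noncoding RNAs KIF5C-AS1 (log2 7.07), MYO16-AS1 (6.39) and SLC26A4-AS1 (5.16) were also higher. Because the use of strand in counting is not given in the sources used here, antisense transcripts cannot be told from their partners.

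In edgeR's test, 5047 genes were higher and 6428 lower in particles among 15,604 tested. With exonic counts only 3941 were higher and 5496 lower, and 1220 of the calls had the other sign. Of 19 tested genes of presynaptic proteins, 18 were higher and 0 lower (18 and 0 adjusted over the list alone), with a median log2 fold change of 3.08. RAB3A (4.64), a vesicle GTPase, SLC17A7 (4.21), the vesicular glutamate transporter of forebrain excitatory neurons, and SYN1 (3.81) led. Camera's adjusted p was 4.65e-08, and adjusted p = 0.444 with an estimated correlation. Of 21 mRNAs known in dendrites or neuropil, 19 were higher and 0 lower, also over the list alone, with a median of 3.12. DDN (5.51), MAP1A (4.73) and NRGN (4.09) led. For this list camera gave an adjusted p of 1.28e-08, and adjusted p = 0.338 with an estimated correlation. Genes of postsynaptic density proteins were split, with 10 higher and 2 lower of 20, the same over the list alone, a median of 0.93 and PPP1R9B (4.21), CAMK2A (3.39) and DLG4 (2.64) in front. These leading genes are also members of the dendritic list. In camera the postsynaptic list had an adjusted p of 0.0128, and adjusted p = 0.548 with an estimated correlation. Without donor 2 hippocampal nuclei it did not pass (adjusted p = 0.0888). All 17 tested genes of kinesins, dyneins and tubulins were higher, also over the list alone, with a median of 2.73 and TUBB (5.04), TUBA1B (4.64), TUBB2A (4.28) and DYNLL2 (3.59) in front. As a list these genes had an adjusted p of 1.28e-08, and adjusted p = 0.118 with an estimated correlation. With exonic counts only, the medians were 2.14 for presynaptic, 2.17 for dendritic, 1.23 for postsynaptic and 1.66 for cytoskeletal genes.

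Transcripts of the protein synthesis and energy machinery were also higher. All 48 tested genes of cytosolic ribosomal proteins were higher, also over the list alone, with a median of 2.52 (RPL15 4.30, RPS23 3.92, RPL4 3.63, RPS20 3.27; adjusted p = 2.16e-15, and adjusted p = 0.338 with an estimated correlation). These genes have many processed copies, which makes single values uncertain, and the median was 0.87 with exonic counts only. Of 39 nuclear-encoded respiratory chain subunits, 34 were higher and 2 lower, the same over the list alone, with a median of 2.19 (ATP5MC3 3.65, ATP5F1B 3.53, UQCRB 3.52, NDUFA4 3.31). Camera gave this list an adjusted p of 9.09e-10, and adjusted p = 0.308 with an estimated correlation. The median was 1.15 with exonic counts only. Immediate early genes, which neurons switch on with activity, had 12 higher and 1 lower of 17, the same over the list alone, and a median of 1.53 (EGR3 4.09, EGR1 3.77, EGR4 3.71, FOSB 2.85; adjusted p = 0.00141, and adjusted p = 0.308 with an estimated correlation). With exonic counts only the adjusted p was 0.129. Replication-dependent histones did not pass as a list (median 1.82, adjusted p = 0.0652, and adjusted p = 0.548 with an estimated correlation). They did with the 3 specimen pairs, which is the fit without donor 2 cortical particles (adjusted p = 0.0213), against neuron-like nuclei only (0.0275) and in 3 of the other 6 fits with a specimen left out. Of these genes, 5 of 7 were higher and 1 lower (6 and 1 adjusted over the list alone), among them H4C3 (3.92), H1-4 (3.45), H1-2 (2.60) and H2BC12 (1.82) against H2AC6 (-1.93). The only blood cell gene tested, HBB, which encodes beta-globin, was 36.6-fold higher (log2 5.19, adjusted p = 0.000243), on 45 UMIs in particles and 6 in nuclei. As shares of all UMIs, blood cell genes stood at 30.5 CPM in 1 particle specimen and at 3.27 to 6.74 CPM in the other 3, so 1 specimen carries much of this fold.

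Nuclear and glial transcripts made up most of the lists that were lower in particles. Of 12 nuclear-retained long noncoding RNAs, 10 were lower and 1 higher, the same over the list alone, with a median log2 of -2.80. NEAT1 (-4.86) and MALAT1 (-4.52), which sit in paraspeckles and nuclear speckles, LINC-PINT (-4.03) and FTX (-3.12) led, whereas OIP5-AS1 was higher (3.31) and GAS5 lay at -0.21 (adjusted p = 0.598). Camera's adjusted p was 0.00405, and adjusted p = 0.308 with an estimated correlation. Of 4 small nuclear and 7SK RNAs, RNU4-2 (-2.22) and RNU4-1 (-1.59), both of the spliceosome, were lower, also over the list alone, and 7SK (-0.28) and RNU1-1 (-0.59) did not pass. The list did not pass either (median -1.09, adjusted p = 0.190, and adjusted p = 0.548 with an estimated correlation). With exonic counts only it did (median -2.98, adjusted p = 0.00461). Small nuclear RNAs have many copies. Neuronal genes over 500 kb long had 16 lower and 0 higher of 20 (17 and 0 adjusted over the list alone) and a median of -2.63, with FHIT (-4.50), CTNNA2 (-2.86) and LRP1B (-2.82) in front. Tested as a list, these genes had an adjusted p of 1.22e-05, and adjusted p = 0.444 with an estimated correlation. With exonic counts only, that median was 0.59 and the adjusted p 0.129.

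Of 14 myelin and oligodendrocyte genes, 11 were lower and 2 higher, the same over the list alone, with a median of -3.25 (CLDN11 -4.22, TF -4.08, ENPP2 -3.64, MAG -3.46). The camera test of this list gave an adjusted p of 0.00398, and adjusted p = 0.444 with an estimated correlation. The 2 that were higher were MBP (0.97, adjusted p = 0.0189), which encodes myelin basic protein, and ERMN (0.92, adjusted p = 0.0223). Of 12 microglia genes, 8 were lower and 0 higher, also over the list alone, with a median of -2.16 (DOCK8 -4.76, ITGAM -4.20, CSF1R -3.39, P2RY12 -2.67). For this list camera gave an adjusted p of 0.0142, and adjusted p = 0.548 with an estimated correlation. Astrocyte genes had 5 higher and 2 lower of 13 (4 and 2 adjusted over the list alone), led by CLU (3.09), GFAP (2.45), SPARCL1 (1.92) and APOE (1.13), and the list did not pass (median 0.57, adjusted p = 0.333, and adjusted p = 0.799 with an estimated correlation). It passed without hippocampal nuclei (adjusted p = 0.0194) or particles (0.0329) of donor 2, and its median was -0.61 with exonic counts only. Vascular cell genes had 2 higher and 3 lower of 10, the same over the list alone. RGS5 (2.25) and ADGRF5 (1.97) were higher, PDGFRB (-2.43) was lower, and CDH5 (1.57) and FLT1 (0.94) did not pass (median 0.79, list adjusted p = 0.578, and adjusted p = 0.799 with an estimated correlation). Nuclei included glia. Against neuron-like nuclei only, the medians were -1.33 for myelin (adjusted p = 0.409), -0.90 for microglia (adjusted p = 0.566), 0.32 for postsynaptic density (adjusted p = 0.409) and 2.38 for astrocyte genes (adjusted p = 0.000153). The first 3 calls ended there. No list passed with an estimated correlation, where 3 residual degrees of freedom leave little power. The estimate lay above the preset correlation for every called list except kinesins, dyneins and tubulins. The list p-values with the preset can therefore be too small.

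**Figure D3:**
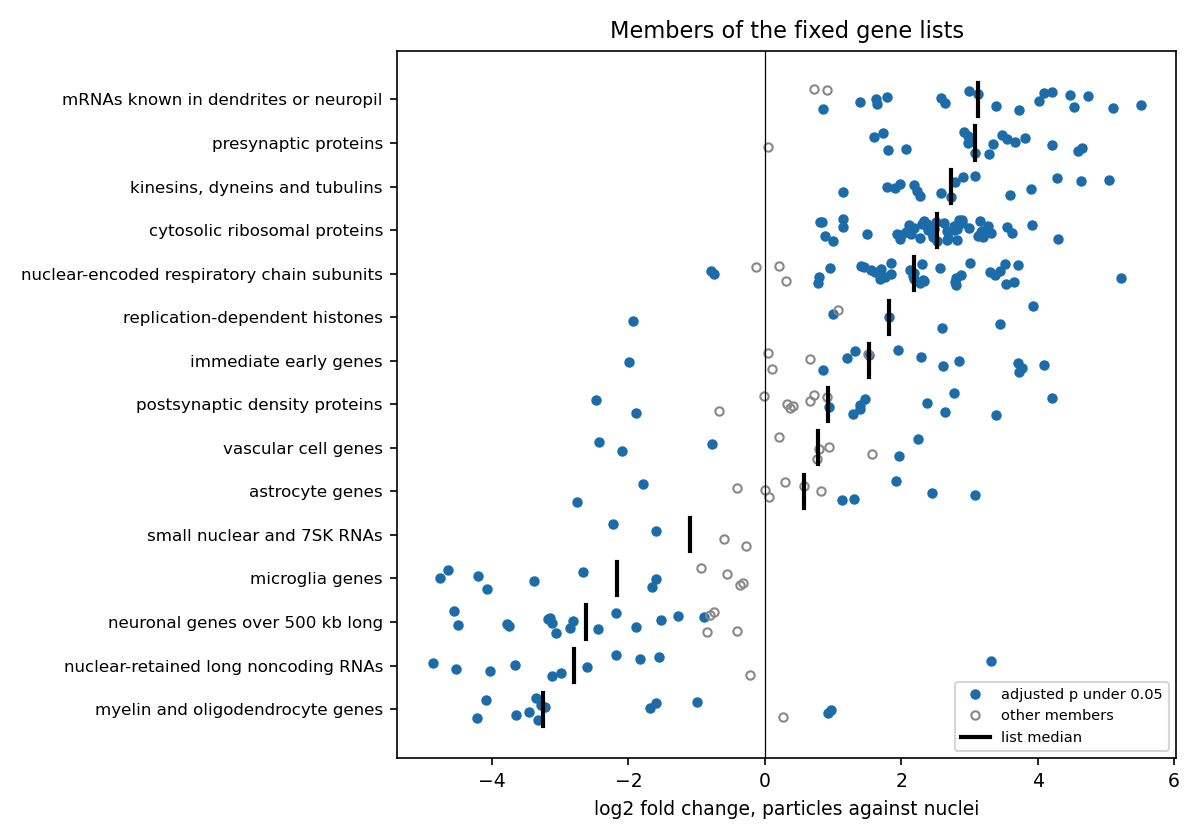
Log2 fold change of particles against nuclei (x axis) for each member of the gene lists with at least 2 tested members (y axis); filled points passed the gene test, open points did not, and black bars mark list medians. The median runs from -3.25 for myelin and oligodendrocyte genes to 3.12 for mRNAs known in dendrites or neuropil.

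Particles with at least 100 genes formed 12 clusters, of which 8 could be named. Astrocyte-like particles made up 44.9% of donor 1 and 19.6% of donor 2 hippocampal particles, and 13.0% and 4.23% of cortical ones. Of these in donor 1 hippocampus, 1416 of 2168 lay in cluster 2, which had 5 of 12 astrocyte markers up and none among its leading genes, beside the highest level of excitatory neuron markers of any cluster (13,948 CPM). At resolution 2 the astrocyte-like share of donor 1 hippocampus was 13.1%. Excitatory neuron-like particles made up 45.2% and 26.9% of cortical particles of donors 1 and 2. The other named clusters were inhibitory neuron-like (1.24% to 3.48% per specimen), oligodendrocyte-like (2.22% to 7.14%), endothelial or mural-like (0.456% to 9.82%; 0.0621% to 0.982% at resolution 0.5) and microglia-like (0.227% to 1.22%). Clusters 1, 3, 4 and 7 stayed unnamed and held 45.5%, 33.1%, 59.9% and 52.7% of particles in donor 1 hippocampus, donor 1 prefrontal cortex, donor 2 hippocampus and donor 2 prefrontal cortex, or 47.3% of all particles (Wilson 95% interval 46.3 to 48.2). Cluster 10, the endothelial or mural-like one, held more UMIs of pan-neuronal than of endothelial or mural markers (10,708 and 2797 CPM). Some cluster-leading genes differ between regions, the Hoechst gate and shallow depth bear on every share, and other clustering settings gave the same class to 27.3% to 78.9% of particles, so sizes were not compared between regions.

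Hippocampal against cortical particles asks which transcripts outside the nucleus differ between regions. Hippocampal particles carried transcripts that cortical particles nearly lacked, and the reverse. FNDC1, a fibronectin type III domain protein gene, had 708 UMIs in hippocampal and 1 in cortical particles, a ratio of 637 after depth (95% counting interval 114 to 25176), and TSPAN18, a tetraspanin gene, 711 and 3 (213, interval 72.6 to 1036). KIT, the receptor of stem cell factor (log2 5.32, 400 ± 45.1 against 9.10 ± 5.46 CPM, SD, n = 2 and 2), FZD7, a Wnt receptor (5.66), SHISA6, an auxiliary AMPA receptor subunit (5.38), SLC24A3, a sodium-calcium exchanger (5.32), FIBCD1 (6.19), CTXND1 (5.43), SLA (4.88) and IGSF10 (4.76) were also higher in hippocampal particles. TESPA1 had 2701 UMIs in cortical and 2 in hippocampal particles (ratio 1502, interval 415 to 12410), MCHR2, a receptor of melanin-concentrating hormone, 175 and 2 (97.3, 26.5 to 810), LINC00507 197 and 1 (219, 38.9 to 8698) and LINC01007 230 and 0, at least 85.3-fold higher in cortical particles. FREM3 (-5.83), KCNH5, a potassium channel gene (-5.37), SYT2, a calcium sensor of fast release (-5.04), SLC17A6, a vesicular glutamate transporter (-4.98), IPCEF1 (-4.82) and PART1 (-4.57) were lower in hippocampal particles on the log2 scale. The adjusted p of these genes was at most 5.32e-06 (IGSF10).

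**Figure D4:**
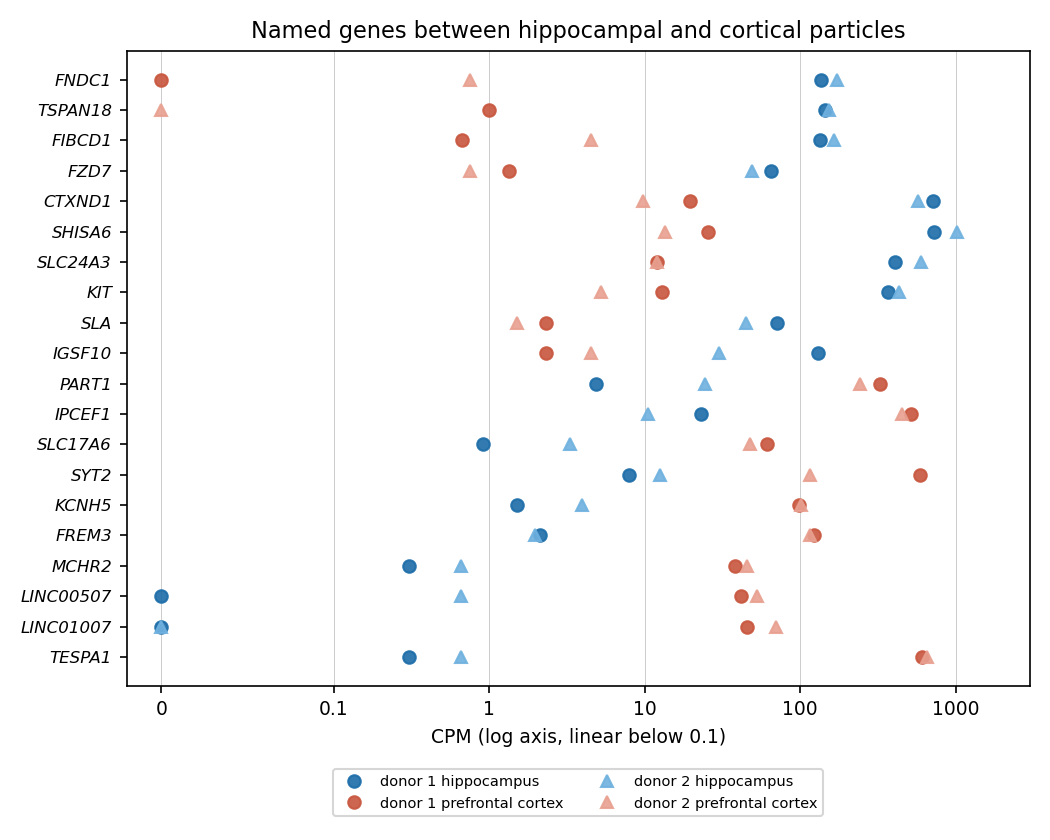
CPM of the 20 named genes (y axis) in particles of 4 specimens, on a log x axis that is linear below 0.1; each symbol is a specimen, with no error drawn. KIT averages 400 CPM in hippocampal and 9.10 in cortical particles, and TESPA1 0.480 and 631.

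In edgeR's test, 950 genes were higher and 962 lower in hippocampal particles among 12,003 tested. With the libraries of each donor alone, 1418 of 3975 genes tested in both donors were called in both, 1339 of them in the same direction. These fits use technical libraries as replicates, so their calls measure the spread between libraries only. Of 21 mRNAs known in dendrites or neuropil, 14 were higher and 2 lower (14 and 3 adjusted over the list alone; median 0.83), with BDNF, a neurotrophin (1.98), PSD (1.41), SHANK1 (1.34) and PPP1R9B (1.23) in front. Camera gave this list an adjusted p of 2.14e-06, and adjusted p = 0.553 with an estimated correlation. Genes of postsynaptic density proteins had 9 higher and 2 lower of 20 (11 and 3 adjusted over the list alone; median 0.53), among them the AMPA receptor subunit GRIA1 (2.17) and CAMK2B (1.24). The camera test of this list gave an adjusted p of 2.66e-05, and adjusted p = 0.553 with an estimated correlation. Astrocyte genes had 8 higher and 1 lower of 12 (9 and 1 adjusted over the list alone; median 1.18), with APOE (2.64), GFAP (2.04), SLC1A2 (1.53) and GJA1 (1.51) in front. For this list camera gave an adjusted p of 2.66e-05, and adjusted p = 0.646 with an estimated correlation. Myelin and oligodendrocyte genes had 3 higher and 0 lower of 13 (4 and 0 adjusted over the list alone; median 0.74), among them MYRF (1.39) and TF (1.38). In camera this list had an adjusted p of 0.00601, and adjusted p = 0.553 with an estimated correlation. Cytosolic ribosomal proteins had 4 higher and 0 lower of 48, also over the list alone (median 0.24; RPLP0 1.18, RPS2 1.08, RPL27A 0.95, RPL4 0.77). In camera this list had an adjusted p of 0.0120, and adjusted p = 0.553 with an estimated correlation. Replication-dependent histones had 1 higher, H2AC6 (1.89), and 0 lower of 7 (4 and 0 adjusted over the list alone; median 1.22, adjusted p = 0.0206, and adjusted p = 0.553 with an estimated correlation).

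Vascular and long neuronal genes lay on the cortical side. Vascular cell genes had 0 higher and 3 lower of 8, also over the list alone (median -0.84; ADGRF5 -3.84, FLT1 -1.45, RGS5 -1.31; adjusted p = 0.0154, and adjusted p = 0.553 with an estimated correlation; 0.153 with exonic counts only, 0.25 with no donor term), beside vascular levels of 61.6 and 264 CPM in hippocampal and 185 and 492 CPM in cortical particles of donors 1 and 2, as shares of all UMIs. Neuronal genes over 500 kb long had 0 higher and 6 lower of 20 (2 and 8 adjusted over the list alone; median -0.44), with SGCZ (-2.06), CDH13 (-1.55), DPP10 (-1.48) and PTPRD (-1.20) in front. As a list these genes had an adjusted p of 0.000497, and adjusted p = 0.553 with an estimated correlation. Lists that did not pass were presynaptic proteins (2 higher and 3 lower of 19, 3 and 3 adjusted over the list alone, adjusted p = 0.852; CPLX1 -1.32, STX1A -0.65, SYT1 -0.57), respiratory chain subunits (0 and 0 of 39, also over the list alone, 0.891), nuclear-retained long noncoding RNAs (1 and 1 of 11, also over the list alone, 0.345), small nuclear and 7SK RNAs (0 and 0 of 4, also over the list alone, 0.915) and microglia genes (1 and 0 of 6, also over the list alone, 0.296; CD74 1.14). Immediate early genes (5 and 4 of 16, 6 and 5 adjusted over the list alone, 0.669; NR4A1 -2.0, DUSP1 -1.80), whose median of -0.01 and camera direction differed in sign, and kinesins, dyneins and tubulins (2 and 3 of 17, 2 and 4 adjusted over the list alone, 0.655; STMN1 -1.89, KIF5A -0.88, KIF3A -0.67) did not pass either, and no blood cell gene was tested. DESeq2 called 382 and 386 genes, and with no low-count filter the counts were 33 and 34. With sums per library, the ribosomal (adjusted p = 0.0563), myelin (0.512) and vascular (0.110) lists did not pass and the histone list was not tested. The tissue field of donor 2 hippocampal particles names cortex against their titles. Particle cluster 7 held 388 hippocampal and 0 cortical particles of donor 2 by title, beside 434 and 2 of donor 1.

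The same regions were compared in nuclei of donor 1 only, with 1 specimen each, so there is no replicate check and no test. Among excitatory neuron-like nuclei (clusters 10 and 11 for hippocampus, 13 for cortex), 763 of 11,665 genes were over 2-fold higher and 724 over 2-fold lower in hippocampus. PARD3, a polarity gene, was 19.5-fold higher in hippocampus (95% counting interval 17.6 to 21.6), ADRA1A, an adrenergic receptor gene, 16.8-fold (15.1 to 18.7), CHST9 25-fold, MCOLN3 27.2-fold, COL6A3 24.4-fold and P2RX2, an ATP-gated channel gene, 23.5-fold, followed by ABCA13, IGSF1, POSTN and LINC01804 at 15.6-fold to 17.9-fold. In cortex, LINC02306 was 157-fold higher (89.7 to 304), DLGAP1-AS4 47.6-fold, MCHR2 46.2-fold (25.7 to 93.0), LINC01378 23.4-fold and LINC01090 21.7-fold, with LINC02217, LINC02055, ADTRP and MDFIC at 11.3-fold to 13.2-fold. Inhibitory neuron-like nuclei (cluster 9) had 117 and 87 of 7787 genes over 2-fold higher and lower. TLL1 (7.92-fold), GLI3 (6.47-fold), C3 (5.48-fold) and SAMD3 (5.01-fold) led in hippocampus and EPIC1 (12.7-fold), LINC02055 (9.59-fold), CBLN2 (6.81-fold) and LINC01378 (5.81-fold) in cortex. TLL1 and SAMD3 were also leading genes of excitatory neuron-like cluster 10 and CBLN2 of cluster 13. GLI3 was one of astrocyte-like clusters 3 and 7, and C3 of microglia-like cluster 4. LINC02055 and LINC01378 were higher in cortical excitatory neuron-like nuclei as well. Free RNA in droplets and doublets (9.93% of cluster 9 by Scrublet) therefore stay open for this class. In glia-like classes, genes over 2-fold higher and lower numbered from 40 and 43 of 4542 in oligodendrocyte precursor-like to 126 and 145 of 7300 in oligodendrocyte-like nuclei. Their leading genes included ADRA1A and CBLN2, which also led among neurons, so free RNA in droplets stays open there. Of 1659 region calls in particles that were compared in excitatory neuron-like nuclei, 1420 (85.6%) had the same direction (Spearman's rho 0.838 across genes, which are not independent replicates). In all nuclei it was 1393 of 1786 (78.0%, rho 0.731). Across 15,604 genes, hippocampal nuclei of donors 1 and 2 correlated with Pearson's r of 0.959 and Spearman's rho of 0.957, and hippocampal and cortical nuclei of donor 1 with 0.951 and 0.948. Within classes, r between the donors was below r between the regions of donor 1 for inhibitory neuron-like (0.895 and 0.966) and oligodendrocyte-like nuclei (0.934 and 0.962). It was above for excitatory neuron-like (0.960 and 0.942), astrocyte-like (0.959 and 0.943) and microglia-like nuclei (0.896 and 0.885), and 0.935 in both for oligodendrocyte precursor-like nuclei. The inhibitory value of donor 2 rests on 29 nuclei, against 248 and 146 in donor 1.

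Double-positive against double-negative particles asks what marks particles that carry both synaptic proteins. DLG4, which encodes PSD95, was higher in double-positive particles (log2 2.21, SE 0.42, adjusted p = 0.000452; 1106 ± 82.5 against 231 ± 87.1 CPM, SD, n = 4 and 4), whereas SYP lay at -0.38 (SE 0.33, adjusted p = 0.492; 947 ± 14.4 against 1345 ± 795 CPM). The 10 named genes on the double-positive side had 0 UMIs in every double-negative library, so their folds are bounds against 3 counts over the group. RIPOR1 was at least 5.18-fold higher, CACUL1 at least 3.31-fold, LDOC1 at least 2.95-fold, WDTC1 at least 2.83-fold, GAD2, which makes GABA, at least 2.77-fold, KLF13 at least 2.76-fold, the mitochondrial kinase gene PINK1 at least 2.75-fold, NLK at least 2.72-fold, GLUD1, a glutamate dehydrogenase gene, at least 2.71-fold and NF2 at least 2.70-fold. On the double-negative side were the guidance genes DCC (-4.10; 214 ± 62.3 against 3276 ± 4800 CPM) and SEMA3E (-5.95), the adhesion gene CNTN5 (-4.14), DKK2 (-4.10), ASTN2 (-3.91), BRI3 (-3.62), HFM1 (-3.59), DNAJC1 (-3.55) and the long noncoding RNAs LINC00486 (-7.69) and C8orf34-AS1 (-3.45), the last an antisense name. Several of these sizes rest on double-negative library 4: without it DCC lay at -1.58 (adjusted p = 0.00817) and SEMA3E at -2.97 (adjusted p = 0.0160), and CNTN5 (-1.78, adjusted p = 0.0872) and BRI3 (-2.47, adjusted p = 0.105) did not pass.

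In edgeR's test, 156 genes were higher and 157 lower in double-positive particles among 2796 tested. Of the 156, 18 had 0 and 36 had 1 to 3 UMIs over the double-negative libraries. Lists were tested here after the data were seen. Of 20 mRNAs known in dendrites or neuropil, 12 were higher and 0 lower, also over the list alone (median 1.62; MAP1A 1.89, CAMK2A 1.81, MAP2 1.6), with adjusted p = 4.65e-07, which held with an estimated correlation (adjusted p = 0.0414). Presynaptic proteins had 7 higher and 0 lower of 19 (9 and 0 adjusted over the list alone; median 0.66; RAB3A 2.37, CPLX2 2.19, BSN 1.14, SLC17A7 0.92). As a list these genes had an adjusted p of 0.0364, and adjusted p = 0.241 with an estimated correlation. Postsynaptic density proteins had 7 higher and 1 lower of 20, the same over the list alone (median 0.47; PPP1R9B 2.71, GRIN2B 1.18, against GRIA3 -1.29). Tested as a list, these genes had an adjusted p of 0.0364, and adjusted p = 0.395 with an estimated correlation. All 3 tested small nuclear and 7SK RNAs were lower, also over the list alone (RNU4-1 -3.38, RNU4-2 -3.07, 7SK -0.98; median -3.07). Camera gave this list an adjusted p of 2.98e-05, and adjusted p = 0.0608 with an estimated correlation. Of 6 myelin and oligodendrocyte genes, MOBP (-2.47) and MBP (-1.63; 7734 ± 447 against 23873 ± 4148 CPM) were lower, also over the list alone (list median -0.49, adjusted p = 0.00237, and adjusted p = 0.241 with an estimated correlation). Neuronal genes over 500 kb long had 0 higher and 7 lower of 17 (0 and 9 adjusted over the list alone; median -0.83; MACROD2 -3.43, LRP1B -2.58, NRG3 -2.02, PTPRD -1.86). The camera test of this list gave an adjusted p of 0.000535, and adjusted p = 0.241 with an estimated correlation.

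The remaining lists did not pass: ribosomal proteins (1 higher and 0 lower of 17, also over the list alone, adjusted p = 0.694), respiratory chain subunits (0 and 0 of 4, also over the list alone, 0.607), nuclear-retained long noncoding RNAs (1 and 1 of 5, 1 and 2 adjusted over the list alone, 0.336; MALAT1 -1.82, OIP5-AS1 1.52), astrocyte genes (2 and 0 of 9, 2 and 1 adjusted over the list alone, 0.740; SLC1A2 0.85, GFAP 0.70), immediate early genes (0 and 0 of 5, also over the list alone, 0.740) and kinesins, dyneins and tubulins (3 and 0 of 15, also over the list alone, 0.651; KIF5A 0.80, TUBB4A 0.70). For the astrocyte and respiratory chain lists, the median was above 0 and camera's direction down. No histone, microglia, vascular or blood cell gene was tested. As shares of all UMIs, vascular cell genes stood at 88.1 CPM in double-positive and 645 in double-negative particles, myelin genes at 8187 and 22842 CPM, and microglia genes at 233 CPM and below the floor of 60.4 CPM. Double-negative libraries were shallow, data simulated for this comparison without an effect (2946 genes) gave 3 called lists of 12, and leaving out a library moved the counts to between 45 and 388 higher and 52 and 154 lower genes. The genes tested moved too, to 338 to 344 without a double-positive library and 4628 to 4724 without a double-negative one. These counts therefore also follow the low-count filter. Of the 157 lower genes, 105 had that direction in all 4 pairs of libraries with the same number, and without double-negative library 4 the sign of 18 calls turned.

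Long noncoding RNAs were compared between neuron-like and glia-like nuclei of the same specimens. In neuron-like nuclei MIR124-1HG, the host transcript of a neuronal microRNA, was 9.27-fold higher (log2 3.21, SE 0.48, adjusted p = 0.00139), at 225 ± 28.2 against 29.9 ± 19.6 CPM (SD, n = 3 and 3). FAM153CP (2.95), LY86-AS1 (2.87), MSC-AS1 (2.86), DLX6-AS1 (2.79), which comes from the DLX locus active in inhibitory neurons, TPBGL-AS1 (2.74), LINC01250 (2.72), LINC02398 (2.65), ANKRD34C-AS1 (2.64) and CCDC144NL-AS1 (2.61) were also higher in neuron-like nuclei. In glia-like nuclei MTUS1-DT (log2 -3.43, adjusted p = 0.000485), PPP1R9A-AS1 (-3.33), OBI1-AS1 (-3.18; 60.5 ± 30.9 against 535 ± 241 CPM), LINC00499 (-3.13), MIR219A2HG (-3.00), EMX2OS (-2.91), CEDORA (-2.90), LINC02649 (-2.90), THBS3-AS1 (-2.89) and HPN-AS1 (-2.87) were higher. MIR219A2HG and HPN-AS1 were also among the 10 named genes that were lower in particles than in nuclei. In edgeR's test, 638 long noncoding RNAs were higher and 726 lower in neuron-like nuclei among 3069 tested. Without donor 1 hippocampus the counts were 286 and 379, and without the pairing by specimen 329 were higher and 559 lower. Antisense names cannot be told from their partners, and free RNA in droplets, whose level was not measured here, adds UMIs of each class to the other.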

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

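The searches for outlying libraries and for a region difference in the particle effect were not among the comparisons fixed before the data were examined. In the median number of UMIs per nucleus, library 2 of donor 2 hippocampal nuclei was lowest of 4, at 2029 against 2284.5 in the nearest library. In the median number of genes per particle, library 4 of donor 2 hippocampal particles was highest of 7, at 250 against 211 in the nearest. With 28 combinations of group and measure examined over 7 groups, chance alone picks out about 1 in 20 groups per measure. The log2 effect of particles against nuclei differed between regions for TSPAN18, by -7.67 when the hippocampal effect is subtracted from the cortical one (SE 0.63, adjusted p = 0.010 in edgeR's interaction test). It was the only gene of 16,838 tested with adjusted p under 0.05, against 1321 with unadjusted p under 0.05. TSPAN18 had 3 UMIs in all cortical particles, so this size rests on the smallest counts.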

How the results depend on the processing

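The fits added after the data were seen are named as such in the methods. For particles against nuclei, counts of higher and lower genes stayed within 1.5 times under every alternative run, from 3808 to 5196 higher and 4560 to 8390 lower. With the specimen as replicate block over 3 pairs they were 5196 and 6691, and with no replicate block 4633 and 5560, and leaving out a specimen gave 4097 to 5196 and 5648 to 7200. Exonic counts only gave 3941 and 5496, with 1220 of the main calls of the other sign, and turned the long-gene list from lower to higher (adjusted p = 0.129), a setting that by construction leaves out introns. With an estimated correlation 0 of 11 lists remained called for particles against nuclei, 0 of 8 for regions and 1 of 6 for sorted particles. The first 2 fits have 3 and 1 residual degrees of freedom, so their lost calls do not decide on correlation. For regions, the dendritic list had an estimated correlation of -0.048, below the preset 0.01, yet camera's p rose from 1.43e-07 to 0.109. Other called lists for regions lay on both sides of the preset. For particles against nuclei, every called list except kinesins, dyneins and tubulins had an estimated correlation above the preset, the dendritic list included. All called lists of the sorted particles did too. Where the estimate lies above the preset, the p with the preset can be too small. For regions in particles, no low-count filter gave 33 higher and 34 lower genes, DESeq2 382 and 386, sums per library 1529 and 1555 (4 lists called), and donor 1 libraries alone 1743 and 1679. With no replicate block for donor the counts were 646 and 665. Leaving out a library gave 795 to 1144 and 752 to 1158. For sorted particles, higher genes numbered 1190 with no low-count filter and 20 at equal depth, and lower genes 240 with DESeq2, 78 with barcodes of at least 200 genes and 25 at equal depth. With the library number as replicate block 149 were higher and 46 lower. Numbers do not pair these libraries (correlations 0.00581, -0.00254, -0.00328 and -0.0151, and 0 of 8 correlate best with their own number). Leaving out a library gave 45 to 388 higher and 52 to 154 lower: 52 and 53 without double-positive library 1, 45 and 61 without 2, 45 and 60 without 3 and 50 and 52 without 4, and 335 and 151 without double-negative library 1, 329 and 143 without 2, 361 and 154 without 3 and 388 and 101 without 4. Fits without a double-positive library tested 338 to 344 genes and those without a double-negative one 4628 to 4724, against 2796 in the main fit. The counts therefore also follow the low-count filter. Without double-negative library 4, 18 of the main calls had the other sign. With no low-count filter 12 did, and 71 of the 157 lower calls were shared. In every other alternative for these particles at most 2 calls turned. For long noncoding RNAs, no replicate block gave 329 higher, and leaving out a specimen 286 to 465 higher and 379 to 555 lower, with 286 and 379 without donor 1 hippocampus. Apart from the fits with fewer samples, UMIs or genes, the cause was not tested. Neuron-like shares moved to 16.2% (resolution 2) in donor 1 hippocampus, 34.0% (clustered alone) in donor 1 prefrontal cortex, and 9.48% (resolution 0.5), 7.0% (resolution 2) and 10.8% (alone) in donor 2 hippocampus. Unnamed particles made up 51.4% at resolution 0.5, 59.1% at 2, 61.3% with at least 200 genes and 37.4% clustered alone. Species purity was 45.5% and 21.4% at 80% and 95%, and 96.3% and 96.9% for barcodes of at least 1000 and 5000 UMIs. The intronic gap was 69.7 and 70.9 percentage points under both alternatives run. Named genes kept their direction in every alternative counted and able to test them, which leaves out equal depth and, for most named genes of sorted particles, the fits without a double-positive library: of 1077 gene and setting pairs for particles against nuclei 0 lost their call, of 751 for regions 6, of 182 for sorted particles 6 and of 200 for long noncoding RNAs 2. Fits without a region sum of particles had no residual degrees of freedom and were not run, for genes and lists; removing mitochondrially encoded genes, and nuclei under 500 genes, changed nothing because there were none. No other call of a count was moved by a block over 1.5 times. Depth limits the sorted comparison: at 49,638 double-negative UMIs, 2796 genes were tested.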

Other observations

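Of the tests in this part, the ones on mitochondrial copies in HEK293T barcodes, on nuclear RNA in the double-negative sort and on splits of lists for the sorted particles were set before their result was seen; those on exonic counts, neuron-like nuclei, equal depth, cluster matches and all other splits were chosen after. In particles, a small set of genes held most of its UMIs in introns although 7.54% of all particle UMIs were intronic on average. These genes were picked after their values were seen: SYT3, a synaptotagmin gene, at 93.2% in particles and 92.7% in nuclei, ZNF483 at 71.7% and 82.7%, KCNA2, a potassium channel gene, at 67.8% and 70.1%, and ADRA1A at 80.4% and 87.5%. With KIF5C-AS1 (99.99%) among them, the 10 leading genes held 11.6% of all intronic UMIs of particles. KIF5C itself was higher in particles by a log2 fold change of 1.79 (adjusted p = 8.84e-05). Overlapping genes in such introns cannot be told apart here.

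Unnamed particle clusters 3, 4 and 7 held mostly hippocampal particles and were led by FIBCD1 and CTXND1, by IGSF1, FAT4 and PDYN (prodynorphin), and by TSPAN18, KIT and FNDC1. Over 6756 genes, their profiles correlated best with nuclear clusters 11 (Spearman's rho 0.317), 15 (0.559) and 11 (0.458), which are excitatory neuron-like and mostly hippocampal, so 3 of 3 clusters matched such nuclei. A candidate source of these particles may therefore be hippocampal excitatory neurons. The match was tested on the same data that gave the clusters, and their leading genes are partly those that differ between regions, so it stays a hypothesis.

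Nuclear pseudogene copies of mitochondrial genes were higher in particles: 26 of 27 tested, with a median log2 fold change of 6.77, against 125 of 190 other pseudogenes with a median of 3.35. They took 0.528% of particle and 0.00862% of nuclear UMIs. Fewer intronic reads in particle totals account for part of this fold at most, since the median fell from 6.77 to 4.90 with exonic counts only. Reads of mitochondrial transcripts placed on the copies remain a candidate explanation: in 98 HEK293T barcodes of the mixed library, the share of UMIs on 38 copies followed that on 27 mitochondrial genes with a Spearman's rho of 0.595 and Pearson's r of 0.748 (permutation p = 1e-05, the smallest that 100000 permutations can give). A true difference in copy transcription between nuclei and particles was not tested.

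Neuronal genes over 500 kb were lower in particles, with a list median of -2.63. Against neuron-like nuclei only, the median was -2.57. Glia would tend to dilute neuronal genes in the nuclear sums. Leaving them out could therefore hardly weaken the fall, and this fit does not decide on cell makeup. Intronic reads of unspliced RNA in nuclei are a candidate explanation, since with exonic counts only the median was 0.59. A difference in the spliced transcripts themselves stays open.

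Genes lower in double-positive than double-negative particles numbered 157. The difference in depth does not account for all of them, since 25 genes, 22 of them among the 157, were lower with double-positive libraries thinned to the depth of the double-negative ones. Only 124 genes could be tested at that depth, against 2796 without thinning, so the test does not reach most of the 157. Nuclear RNA in the double-negative sort cannot be told apart from other sources: these genes had a median log2 fold change of -0.13 in particles against nuclei (quartiles -1.84 and 3.1), with 65 higher in nuclei and 61 in particles, against a median of 2.19 for the 156 genes higher in double-positive particles and 1.04 for the 2483 tested and not called. The myelin and vascular levels of the double-negative sort, and the biological difference between the sorts, stay open as untested.

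Other splits of the samples were counted for each fit that allowed it. For genes called between particles and nuclei, the real split gave 11475 and the highest other 3852, and 1 of all 35 splits gave as many. The tissue pairs nuclei and particles of 3 shared specimens, and the 8 splits that part all 3 pairs are too few for a share under 0.05. The highest other is among those 8: it exchanges nuclei and particles of the 3 shared specimens and leaves donor 2 cortical particles with the nuclei. For lists between particles and nuclei the splits do not exclude chance, as 17 of 35 gave as many as the real 11 and the highest other gave 15. The other splits leave the true fraction out of the fit, so its effect can enter them, and they cannot decide. In data simulated for this comparison without an effect, camera called 0 of 15 lists. Genes were drawn independently there, so this cannot show whether correlated genes add calls. For genes of the sorted particles the real split gave 313 and the highest other 4, with 1 of 35 splits as many. This covers the libraries of 1 specimen only. The real split also parts deep from shallow libraries (246343 to 442453 against 9442 to 18725 UMIs), and every other split mixes them. The splits therefore cannot tell the sort from depth and are not read as excluding chance. Chance differences between sorts or donors were not tested. For lists of the sorted particles the real split gave 6 and the highest other 4, with 1 of 35 as many. Camera also called 3 of 12 lists in data simulated for this comparison without an effect (2946 genes), and 1 of 6 remained with an estimated correlation, so these list calls stay open. For long noncoding RNAs 10 splits are too few for a share under 0.05, with 1364 in the real split and 0 as the highest other.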
